A study of Mus musculus with 6 samples.

How the data were processed

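RNA sequencing of mouse hippocampus was analysed in 6 libraries, 2 each of Control, PIA and PIA+IL-27. Samples were grouped by the treatment given in the labels, and the columns of the table were joined to the samples through the library names in the labels. The deposited table gives an expected count per gene and library, estimated by the authors per the file headers; 11.3 to 13.3% of the values are not whole, counted exactly, without a tolerance. The authors' normalized read count is a signal equal to the read count, rounded up, divided by 1 factor per library, and this holds for 100% of the values within a tolerance of 1e-06. The factors run from 0.917 to 1.05. Values in TPM (transcript abundance scaled to a fixed library total) and in FPKM are given per library by the authors over the whole library, per the file headers. The authors also give a log2 fold change, a p-value and a Q value for each of the 3 group comparisons, and the log2 values are additive to 1.07e-14. The aligner, counter, genome build, strand and test are not given in the sources used here.

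All 3733 deposited genes meet an absolute log2 fold change of at least 1 and a Q value of at most 0.05 in at least 1 of the authors' comparisons. The table is therefore a selection made on the same libraries. Adjusted p-values over it do not control the false discovery rate of the genome, and a list is compared with other selected genes only. The reads in the listed genes are part of each library, so the depth of a library was estimated from read counts, lengths and FPKM of 87 genes with a single transcript, an FPKM of at least 3 and a length of at least 2000 bases; it came to 15770813, 14985781, 15719944, 15081962, 14514058 and 15377255 reads in Control 1 and 2, PIA 1 and 2, and PIA+IL-27 1 and 2. In the order of the libraries, 161, 150, 143, 187, 148 and 158 listed genes had 0 reads. Of the gene identifiers, 3702 were found in a RefSeq gene table, 3699 of them with the same symbol. GC content and transcript length were taken from the longest coding transcript of GENCODE for 3545 genes (95.0%).

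Expected counts were rounded and tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test, all 6 libraries in 1 fit, after filterByExpr by group, which left 3216 genes. Results were adjusted by Benjamini-Hochberg with a threshold of 0.05. The plan made before the data were examined named TMM factors. Because the table holds only genes that the authors called in some comparison, the authors' factors for the whole library were used instead, and TMM and median-of-ratios factors over the listed genes became alternatives. Each gene's own spread had no weight in the fit (the prior degrees of freedom were infinite). Gene lists fixed before the data were examined, 16 of which had at least 5 tested genes, were tested by camera with a preset correlation of 0.01, with an estimated correlation, and by fry, adjusted over the lists. No list passed with an estimated correlation or by fry in any comparison; the smallest unadjusted p of fry was 0.0459, for the MHC list in PIA against Control, with an adjusted p of 0.72. The opposite changes of the comparisons that share PIA were set beside 20 simulated sets of unchanged groups, for all 6 libraries and with each library left out. Folds against a group with no reads are lower bounds computed from a floor of 3 counts over the group.

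The rule for named genes, fixed before the data were examined, took per comparison the 10 higher and 10 lower genes with the smallest p among those past the threshold whose groups do not overlap, filled up with the smallest unadjusted p, up to 4 genes per list, and 13 genes in every comparison, of which 1 is not reported here. The test was run on simulated data with the depth and spread of these libraries. At the observed coefficient of variation of 0.597, 0 to 4% of genes changed 2-fold, 0 to 12% of those changed 4-fold, 22 to 46.9% of those changed 8-fold and 61.2 to 87.5% of those changed 16-fold were recovered, with 0 to 6 false calls per comparison among 2827 to 2835 unchanged genes. At a coefficient of 0.1, 78 to 84% were recovered at 2-fold. Of 5 raised lists, camera recovered 3, 5 and 4 in the 3 comparisons, and it called 0 of 20 unchanged lists. Simulated genes were drawn independently, so this holds only for lists of uncorrelated genes. In PIA against Control the estimated correlation was 0.44 for the MHC list and 0.89 for neutrophils and monocytes. The error rate of camera at such correlations was not tested.

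The alternatives planned beforehand were TMM and median-of-ratios factors, no filter on low counts, replicate number as a block, only the libraries of the comparison, each library left out in turn, DESeq2 1.42.0, limma 3.58.1 with a trend on log2 TPM with 1 or 0.1 added, and an estimated correlation for the lists. Chosen after the data were seen were a robust estimate of the spread, loess trends on GC content and length removed per library (span 0.5, fitted on genes with a mean count of at least 20), a term for PIA 2 and PIA+IL-27 1, the fit without these 2, and adjustment over 21900 protein-coding genes. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Raw reads and genes outside the table were not used here. With 2 libraries per group, no other splits of the samples and no test for outlying libraries were run.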

Results

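Gene expression was measured by sequencing of total RNA from mouse hippocampus in 3 groups of 2 libraries each: Control, PIA and PIA+IL-27. PIA is the postnatal immune activation of the study's title, and the design names the same groups as control, LPS and LPS with recombinant IL-27. LPS is bacterial lipopolysaccharide, a stimulus of innate immunity, and IL-27 is a cytokine made by myeloid cells. The comparisons address which genes differed after immune activation, and which differed when IL-27 was added to it. The labels give each library as a separate sample and name no animal, sex or litter, so the p-values cover these samples only. Those of edgeR rest on a spread between samples that is pooled over genes. Those of camera compare the genes of a list with the other listed genes at a preset correlation of 0.01. In them genes, rather than samples, act as the replicates. The deposited table holds 3733 genes, all of which pass an absolute log2 fold change of 1 and a Q value of 0.05 in at least 1 of the authors' 3 comparisons. The table was thus selected on these same libraries, and genes outside it are not analysed here. Reads in the listed genes numbered 648600 and 1533805 in Control 1 and 2, 893359 and 641672 in PIA 1 and 2, and 1593441 and 1386617 in PIA+IL-27 1 and 2. They made up 2.14 to 5.61% of a library's transcripts, as given by TPM values, and the depth of a whole library was estimated at 14514058 to 15770813 reads. Floors given for counts of 0 cover counting error only.

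The libraries of a group differed from each other in several groups of genes. Replicates differed by over 2-fold at 2567 of the 3733 genes (68.8%) in Control, 1173 (31.4%) in PIA and 1157 (31.0%) in PIA+IL-27. Of the 2567 in Control, 2131 were higher in Control 2. The first principal component held 53.6% of the variance and put Control 1 and both PIA libraries on one side, and Control 2 and both PIA+IL-27 libraries on the other. The table was selected on these libraries, with 2974 genes listed for PIA+IL-27 against PIA. Such a selection favours genes with a split between PIA and PIA+IL-27. It may also favour close replicates in these groups, but the authors' test is not given. The shares and the component therefore describe the listed genes only. Across genes, Control 1 correlated at 0.937 with PIA 1 and at 0.868 with Control 2. Across genes, which are not independent replicates, the log2 ratio of Control 2 to Control 1 followed GC content with a Spearman rho of -0.55, and that of PIA+IL-27 to PIA with a rho of -0.65. Transcripts of 4 Y-linked genes summed to 541 and 594 normalized read counts in PIA and 1476 in PIA+IL-27 1, against 2.94 and 9.52 in Control and 6.80 in PIA+IL-27 2. Transthyretin (Ttr), the main secreted protein of the choroid plexus, had 78.4 and 58611 normalized read counts in Control, 11302 and 141 in PIA, and 6.26 and 649 in PIA+IL-27. Of the 5 listed neocortical markers, 3 were higher in both PIA 2 and PIA+IL-27 1 than in every other library, and 3 of the 4 listed markers of dentate granule cells were lower in both than in every other library. Prox1, a transcription factor of dentate granule cells, had 96.0 and 172 normalized read counts in these libraries and 590 to 1358 in the other 4.

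**Figure D1:**
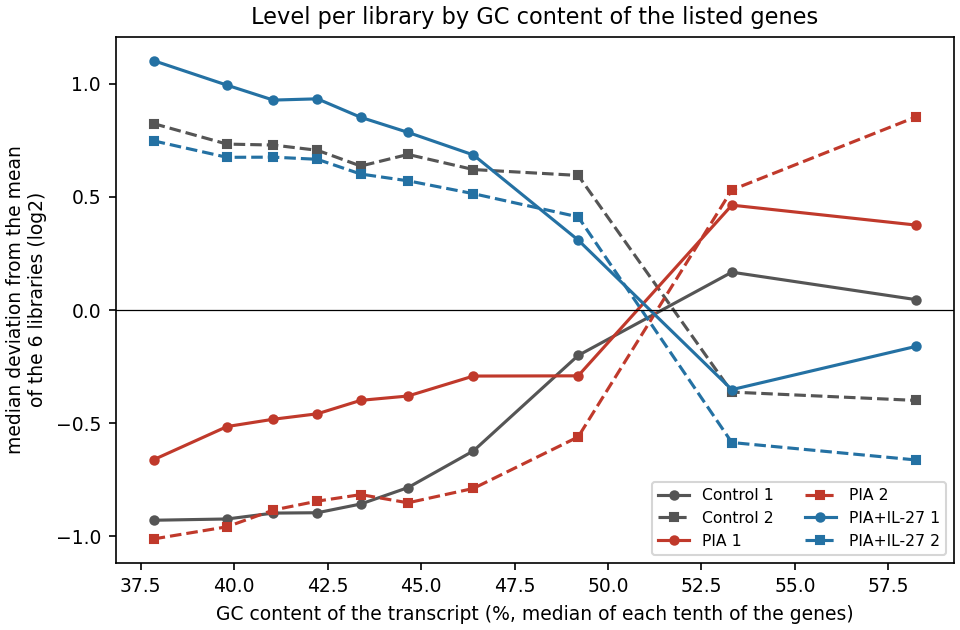
Median deviation (log2) of gene expression from the mean of the 6 libraries, by bin of GC content (percent), for 2575 genes with a mean count of at least 20. In the third of genes with the lowest GC content, Control 1, PIA 1 and PIA 2 lay at -0.92, -0.55 and -0.95, and Control 2, PIA+IL-27 1 and PIA+IL-27 2 at 0.75, 0.99 and 0.70.

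Genes of antigen presentation and of the response to interferon gamma were higher in PIA than in Control. All 17 genes of this list had more normalized reads in both PIA libraries than in either Control library. Chance gives such a separation in either direction for 33.3% of unselected genes. Among the genes that the authors list for this comparison, 50.4% separated in either direction. The median log2 fold change of the 17 genes was 1.88 (adjusted p = 1.31e-17, camera). The call was lost with adjusted p = 0.449 with an estimated correlation. Nlrc5, the activator of MHC class I genes, had a log2 fold change of 3.38 ± 1.03 (SE, n = 2 per group; adjusted p = 0.204, edgeR), with 38.2 and 12.4 normalized read counts in Control and 90.3 and 440 in PIA. Ciita, the activator of MHC class II genes, had a log2 fold change of 2.83 ± 1.09 (adjusted p = 0.504), and the class II chaperone Cd74 had 97.9 and 35.2 normalized read counts in Control and 211 and 473 in PIA (2.36 ± 0.963, adjusted p = 0.617). No gene of the list passed over all genes tested, and 1 passed when adjusted over the list alone. The list also separated the Control libraries: its median log2 ratio of Control 2 to Control 1 was -1.45, with all 17 genes lower in Control 2, and without Control 1 its median in PIA against Control was 3.02.

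Lists of inflammation were higher in PIA as well. Inflammatory cytokines and NF-kB targets had a median log2 fold change of 1.52 with 14 of 14 tested genes above 0 (adjusted p = 2.51e-09), and type I interferon response genes 1.18 with 16 of 17 above 0 (adjusted p = 1.59e-08). Complement and phagocytosis genes had a median of 1.10 with 9 of 9 above 0 (adjusted p = 6.04e-06), reactive astrocyte genes 1.28 with 10 of 10 (adjusted p = 4.94e-05), and neutrophil and monocyte genes 1.49 with 7 of 7 (adjusted p = 0.000137). For each of these 5 lists, adjusted p = 0.449 with an estimated correlation. Both PIA libraries lay above both Control libraries in 8 of the 16 listed inflammatory genes, 5 of 17 interferon and 4 of 9 complement genes. They did so in 2 of 10 reactive astrocyte and 0 of 8 neutrophil genes. In 0 genes of these lists did both lie below. Among the genes that the authors list for this comparison, 50.4% separated in either direction. No gene of these lists passed over all genes tested; adjusted over the list alone, 1 inflammatory and 1 reactive astrocyte gene passed. The chemokine Cxcl10 had 39.2 and 2.86 normalized read counts in Control and 238 and 124 in PIA (log2 fold change 3.10 ± 1.04, adjusted p = 0.279). Lcn2, the iron-sequestering lipocalin, had 214 and 1.90 in Control and 1496 and 46.9 in PIA (2.84 ± 0.927, adjusted p = 0.278). PIA 1 held the most reads of both genes and of the neutrophil gene S100a8, with 598 normalized read counts against 19.6 in PIA 2. Without PIA 1 the neutrophil list had a median of -1.41 (adjusted p = 0.93) and the reactive astrocyte list -0.78 (adjusted p = 0.93), while the type I interferon, inflammatory and complement lists passed with smaller medians of 0.52, 0.89 and 0.72. Without Control 2 the complement list had a median of 0.60 (adjusted p = 0.414), the interferon list 0.67 (adjusted p = 0.392), the reactive astrocyte list 0.98 (adjusted p = 0.432) and the neutrophil list 0.78 (adjusted p = 0.732), whereas the MHC list passed with 1.34 (adjusted p = 1.01e-08) and the inflammatory list with 1.12 (adjusted p = 0.0045). Without Control 1 the inflammatory, interferon, complement, reactive astrocyte and neutrophil medians were 2.30, 1.97, 2.21, 1.91 and 4.37, and all 5 lists passed.

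Ependyma and choroid plexus genes were lower in PIA than in Control. Markers of ependyma, the ciliated cells of the ventricle wall, had a median log2 fold change of -1.95 with 9 of 9 below 0 (adjusted p = 0.000427; adjusted p = 0.487 with an estimated correlation). Markers of the choroid plexus had -2.32 with 15 of 15 below 0 (adjusted p = 0.00149; adjusted p = 0.568 with an estimated correlation), and 9 of them passed when adjusted over the list alone. Both PIA libraries lay below both Control libraries in 7 of the 9 ependyma and 0 of the 15 choroid plexus genes. Both lay above in 0 genes of either list. All 15 choroid plexus genes were higher in Control 2 than in Control 1, by a median log2 ratio of 3.91; without Control 2 the list's median turned to 1.20 (adjusted p = 0.0128), and without PIA 2 the list did not pass (-1.47, adjusted p = 0.186). Without Control 1 the ependyma list did not pass (-2.57, adjusted p = 0.0603). PIA 2 and PIA+IL-27 1, the libraries with high neocortical and low dentate markers, lay below every other library in 6 of the 9 ependyma and 6 of the 15 choroid plexus genes, and with a term for these 2 libraries neither list passed (-1.03 and -1.63, adjusted p = 0.152 and 0.166). With TMM scaling the ependyma and choroid plexus medians were -1.23 and -1.40. Genes of adult neurogenesis had a median of -1.07 with 5 of 5 below 0 (adjusted p = 0.0298; adjusted p = 0.529 with an estimated correlation). They did not pass without PIA 2 (-0.35, adjusted p = 0.658) or without Control 1 (-1.05, adjusted p = 0.507), nor with GC and length trends removed (-1.02), nor with TMM or median-of-ratios scaling (both -0.80), nor with the term for PIA 2 and PIA+IL-27 1 (-0.51, adjusted p = 0.772). In this list Eomes, a transcription factor of neuronal progenitors, had 122 and 3.27 normalized read counts in PIA 1 and 2.

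The other 7 lists tested did not pass in PIA against Control. The medians were -1.03 for the glutamatergic synapse (adjusted p = 0.0537), -1.24 for GABA neurons and synapse (adjusted p = 0.0656), 0.96 for neocortex (adjusted p = 0.0537), 0.12 for meningeal fibroblasts (adjusted p = 0.092), -0.74 for homeostatic microglia (adjusted p = 0.839), 0.30 for activated microglia (adjusted p = 0.568) and -0.06 for the glucocorticoid response, whose mean was 0.03 (adjusted p = 0.668). With TMM scaling the homeostatic microglia median turned to 0.25 and the glucocorticoid median to 0.32, and the glutamatergic (-0.27) and meningeal lists (0.40) passed. The synaptic lists passed without Control 1 (-1.65 and -1.95, adjusted p = 0.00478 and 0.00908), as did meningeal fibroblasts (0.45, adjusted p = 0.035), and the neocortical list passed without PIA 1 (1.33, adjusted p = 0.00449).

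At the level of single genes, 7 of 3216 tested genes passed in PIA against Control, 5 higher and 2 lower. The higher ones included the Y-linked genes Kdm5d (adjusted p = 1.07e-05), Ddx3y (adjusted p = 2.64e-05), Eif2s3y (log2 fold change 5.54 ± 1.13, adjusted p = 0.000925) and Uty (adjusted p = 0.016). Kdm5d and Ddx3y had no reads in Control and were at least 102-fold and at least 71.9-fold higher in PIA, against a floor of 3 counts over the group. Uty had 0 and 0.952 normalized read counts in Control and 41.3 and 39.3 in PIA. The 4 summed to 2.94 and 9.52 normalized read counts in Control and to 541 and 594 in PIA, so no library of either group has the level of the other, and the comparison of PIA with Control cannot be told apart from this difference. Entpd4, the fifth, was seen in PIA 1 alone of this pair of groups, with 101 normalized read counts. Hmga1b, a near-identical copy of the chromatin protein gene Hmga1, was lower (-5.33 ± 1.14, adjusted p = 0.00188), while the sum of Hmga1 and Hmga1b was 1446 and 973 normalized read counts in Control and 1459 and 1697 in PIA. Gm45855, also lower, had 16.7 and 1048 in Control. Entpd4 and Gm45855 fall outside the rule for named genes and were named after their values were seen. The protease inhibitor Serpina3f (4.19 ± 1.11, adjusted p = 0.0579), the interferon-induced GTPase genes Tgtp2 (3.82, adjusted p = 0.158) and Igtp (2.91, adjusted p = 0.278) and the itaconate enzyme Acod1 (3.38, adjusted p = 0.278) were the next among higher genes and did not pass. Serpina3f and Tgtp2 belong to families of near-identical copies with non-whole read counts.

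The edgeR test called these 7 genes at a biological coefficient of variation of 0.597, and 202 genes had an unadjusted p under 0.05, of which 98 were higher. With factors computed over the listed genes (TMM), edgeR called 0, with 117 at an unadjusted p under 0.05, of which 96 were higher, and the median of all genes moved from -0.68 to -0.00; DESeq2 called 2 and limma 6. Without Control 1 or without Control 2 the count was 0, with 1264 and 46 genes at an unadjusted p under 0.05, without PIA 1 it was 4 and without PIA 2 it was 3. The authors list 1957 genes for this comparison, 673 higher and 1284 lower, and in 986 of them (50.4%) the groups did not overlap.

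**Figure D2:**
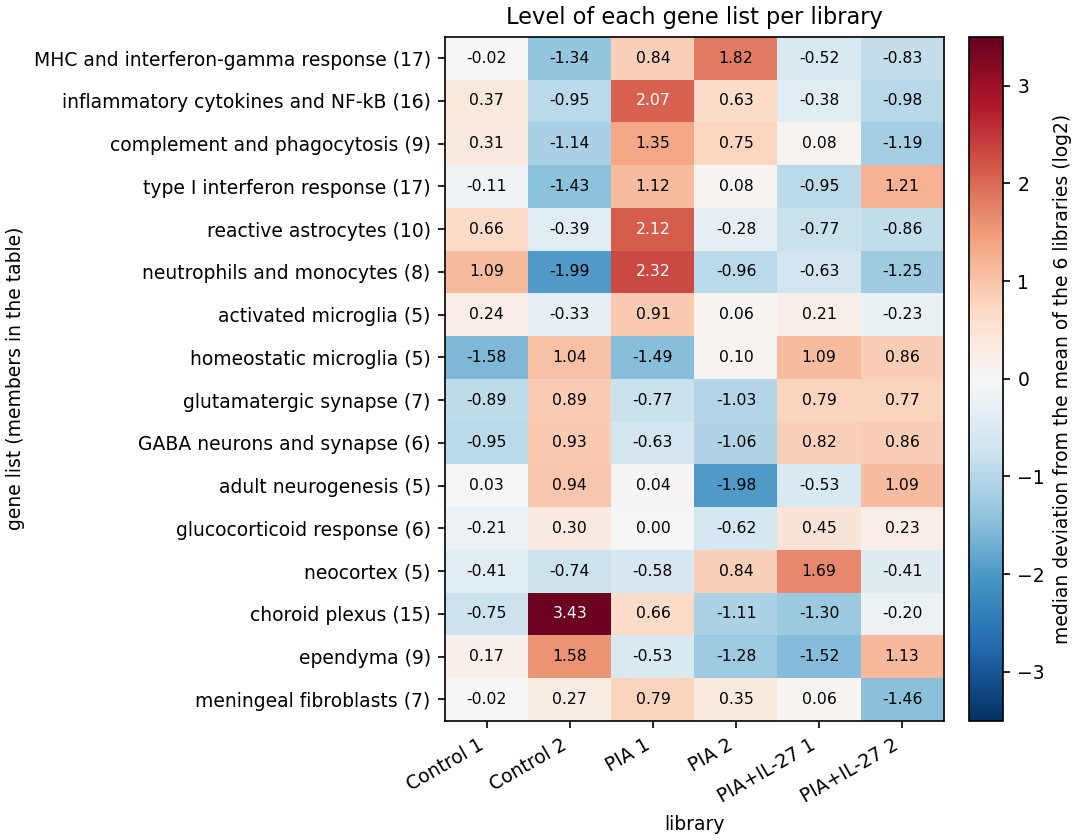
Median deviation (log2) from the mean of the 6 libraries over the genes of each list, by library. The MHC and interferon gamma list lay at 0.84 and 1.82 in PIA 1 and 2, between -1.34 and -0.02 in Control and between -0.83 and -0.52 in PIA+IL-27.

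When IL-27 was added, genes of antigen presentation and inflammation were lower than in PIA. The MHC and interferon gamma list had a median log2 fold change of -2.14 with 17 of 17 genes below 0 (adjusted p = 1.16e-14, camera). With an estimated correlation the adjusted p was 0.345. In 16 of the 17 both PIA+IL-27 libraries lay below both PIA libraries. Among the genes that the authors list for this comparison, 87.0% separated in either direction. No gene of the MHC list passed over all genes tested and 8 passed when adjusted over the list alone. The class II gene H2-Ab1 had 126 and 211 normalized read counts in PIA and 26.1 and 9.71 in PIA+IL-27 (log2 fold change -3.23 ± 1.04, n = 2 per group, adjusted p = 0.175), and the interferon-induced GTPase Gbp2 had 590 and 420 against 78.2 and 82.5 (-2.65 ± 0.941, adjusted p = 0.231). Inflammatory genes had a median of -1.91 with 13 of 14 below 0 (adjusted p = 8.92e-12; adjusted p = 0.345 with an estimated correlation), of which 2 passed over all genes and 5 when adjusted over the list alone. Those 2 were the chemokines Ccl5 (-5.48 ± 1.21, adjusted p = 0.00286), with 271 and 60.01 normalized read counts in PIA and 7.30 and 0 in PIA+IL-27, and Cxcl10 (-4.57 ± 1.13, adjusted p = 0.0174), with 238 and 124 against 7.30 and 7.77. The MHC and inflammatory lists passed without any single library and with GC and length trends removed, where their medians were -1.31 and -1.49. The MHC median was -1.40 without PIA 2, and the inflammatory median -1.17 without PIA 1. With TMM scaling the medians were -3.46 and -3.14.

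The lists of reactive astrocytes, complement, neutrophils and monocytes, meningeal fibroblasts and choroid plexus were lower as well. Reactive astrocyte genes had a median of -1.72 with 10 of 10 below 0 (adjusted p = 2.99e-09; adjusted p = 0.345 with an estimated correlation), with 2 genes passing over all genes and 5 adjusted over the list alone. Complement genes had -1.63 with 9 of 9 below 0 (adjusted p = 4.43e-08; adjusted p = 0.345 with an estimated correlation), with 1 passing adjusted over the list alone. Neutrophil and monocyte genes had -2.44 with 7 of 7 below 0 (adjusted p = 7.65e-07; adjusted p = 0.417 with an estimated correlation), with 1 passing over all genes and 4 adjusted over the list alone. Meningeal fibroblast genes had -1.19 with 6 of 7 below 0 (adjusted p = 0.000404; adjusted p = 0.417 with an estimated correlation), and did not pass without PIA+IL-27 2 (-0.75, adjusted p = 0.0755). Choroid plexus genes had -0.69 with 13 of 15 below 0 (adjusted p = 1.13e-05; adjusted p = 0.487 with an estimated correlation), with 1 passing over all genes and 2 adjusted over the list alone. With TMM scaling the medians of these 5 lists were -2.78, -2.81, -3.5, -2.37 and -1.77. Both PIA+IL-27 libraries lay below both PIA libraries in 5 of the 10 listed reactive astrocyte genes, 6 of 9 complement and 3 of 8 neutrophil genes. The same held for 5 of 7 meningeal and 4 of 15 choroid plexus genes. Both lay above in 1 choroid plexus gene and in 0 genes of the other lists. Lcn2 (-4.86 ± 1.03, adjusted p = 0.00117) and Steap4 (-4.87, adjusted p = 0.0067) were the reactive astrocyte genes that passed, and S100a8, a subunit of neutrophil calprotectin, passed with -3.92 (adjusted p = 0.043). These 3 and Ttr (-4.13, adjusted p = 0.000629) had their most reads in PIA 1 within PIA. Without PIA 1 the neutrophil list had a median of 0.05 (adjusted p = 0.103), the choroid plexus list 0.28 (adjusted p = 0.0569) and the reactive astrocyte list -0.59 (adjusted p = 0.00782).

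Synaptic genes were higher in PIA+IL-27 than in PIA. Genes of the glutamatergic synapse had a median log2 fold change of 1.63 with 7 of 7 above 0 (adjusted p = 0.0208; adjusted p = 0.570 with an estimated correlation), and genes of GABA neurons and synapse 1.76 with 6 of 6 above 0 (adjusted p = 0.0208; adjusted p = 0.562 with an estimated correlation). The median of all 3216 tested genes was 1.17, and the medians of the 2 lists lay 0.46 and 0.59 above it. None of the 13 passed over all genes. Adjusted over the list alone, 3 and 2 passed. The AMPA receptor subunit Gria2 had 627 and 559 normalized read counts in PIA, 2756 and 2610 in PIA+IL-27, and 670 and 3073 in Control (2.18 ± 0.839, adjusted p = 0.257). The GABA receptor subunit Gabrb2 had 202 and 190 in PIA, 1373 and 1060 in PIA+IL-27, and 234 and 983 in Control (2.63 ± 0.896, adjusted p = 0.203). All 13 genes were higher in Control 2 than in Control 1, by a median log2 ratio of 1.78 over the glutamatergic list. With GC and length trends removed the lists had medians of 0.30 (adjusted p = 0.319) and 0.31 (adjusted p = 0.243), and with TMM scaling 0.41 and 0.54. Without PIA 2 the GABA list did not pass (1.65, adjusted p = 0.0725), and without PIA 2 and PIA+IL-27 1 together neither passed (1.72 and 1.62, adjusted p = 0.0741 and 0.0811).

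The type I interferon list passed as lower relative to the other listed genes (adjusted p = 0.0065; adjusted p = 0.573 with an estimated correlation), with 9 genes above 0 and 8 below, a median of 0.05 and a mean of -0.03. In 13 of its 17 genes PIA 1 and PIA+IL-27 2 were higher than the other 4 libraries; Irf7, a transcription factor of this response, had 790 and 396 normalized read counts in these and 21.9 to 358 in the others. The list did not pass without PIA 1 (0.38) or without PIA+IL-27 1 (0.63), nor with TMM or median-of-ratios scaling (both -1.12). With GC and length trends removed it did not pass either (0.09, adjusted p = 0.471, camera). Without PIA+IL-27 2 its median was -1.61. The 6 other lists did not pass: homeostatic microglia 1.49 (adjusted p = 0.482, 1 gene passing adjusted over the list alone), activated microglia -1.15 (adjusted p = 0.200), adult neurogenesis 1.27 (adjusted p = 0.554), ependyma 1.26 (adjusted p = 0.648), neocortex 0.47 (adjusted p = 0.554, tested as lower) and the glucocorticoid response -0.03 with a mean of 0.07 (adjusted p = 0.361). With TMM scaling the neocortex median was -0.92. Ependyma passed as higher without PIA+IL-27 1 (2.14, adjusted p = 0.00597) and as lower without PIA+IL-27 2 (-1.04, adjusted p = 0.0291). It also passed as higher with GC and length trends removed (1.92, adjusted p = 0.00144) and without PIA 2 and PIA+IL-27 1 together (1.77, adjusted p = 0.020). Adult neurogenesis passed without PIA+IL-27 1 (1.41, adjusted p = 0.0447). P2ry12, a purine receptor of resting microglia, had 9.61 and 56.7 normalized read counts in PIA and 258 and 184 in PIA+IL-27 (2.74 ± 0.999, adjusted p = 0.233).

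Among single genes, 14 of 3216 passed in PIA+IL-27 against PIA in the fit of all 6 libraries, 2 higher and 12 lower. The lower ones included acute-phase genes: serum amyloid Saa3 (-5.42 ± 1.03, adjusted p = 0.000168), with 3384 and 96.0 normalized read counts in PIA and 80.3 and 0.971 in PIA+IL-27, and haptoglobin (Hp, -5.67 ± 1.19, adjusted p = 0.00117), with 466 and 9.82 against 6.26 and 2.91. Without PIA 1, Saa3 had a log2 fold change of -1.24 and Hp -1.08. The lower genes also included the protease inhibitors Serpina3f (-4.77 ± 1.15, adjusted p = 0.0125) and Serpina3g (-4.20 ± 1.07, adjusted p = 0.0234), near-identical copies whose sum was 436 and 562 in PIA and 28.2 and 21.4 in PIA+IL-27, and Wfdc17 (-5.42, adjusted p = 0.0184; -2.01 without PIA 1). The chemokine Cxcl9 (-4.91, adjusted p = 0.0511), the interleukin 1 receptor antagonist Il1rn (-4.41, adjusted p = 0.0615) and Tnfaip2 (-3.72, adjusted p = 0.0835) were the next and did not pass. Gdf1, the twelfth lower gene, had non-whole read counts in all 6 libraries. The higher genes were Hmga1b (6.20 ± 1.18, adjusted p = 0.000168), whose sum with Hmga1 was 1087 and 1006 normalized read counts in PIA+IL-27 against 1459 and 1697 in PIA, and Gm45855. Zfp738, a zinc finger gene (3.86, adjusted p = 0.139), and 8 others named by the rule, among them Zfp979, Zfp72 and Zfp40, did not pass. Gdf1 and Gm45855 fall outside the rule for named genes in this comparison and were named after their values were seen.

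Of the 3216 genes, 602 had an unadjusted p under 0.05 in edgeR, 462 of them higher, and the median log2 fold change of all genes was 1.17. With TMM over the listed genes, edgeR called 0, with 591 at an unadjusted p under 0.05 of which 90 were higher, and the median was -0.04; DESeq2 called 4 and limma 9. In the fit of all 6 libraries, the spread included the Control pair, which is not part of this comparison. Replicates differed by over 2-fold at 68.8% of listed genes in Control, 31.4% in PIA and 31.0% in PIA+IL-27. The selection of the table may favour close replicates in PIA and PIA+IL-27, though the authors' test is not given. A spread taken from these groups alone may therefore be too small. Tested on the 4 libraries of this comparison alone, 449 genes passed, 414 higher and 35 lower. The count was 0 without Control 1, Control 2 or PIA 1 (1602, 1589 and 92 genes at an unadjusted p under 0.05), 7 without PIA 2, 5 without PIA+IL-27 1, and 3 without PIA+IL-27 2, which leaves the libraries with Y-linked transcripts in this comparison. In that last fit the MHC list had a median of -1.99 (adjusted p = 1.34e-10). The PIA and PIA+IL-27 libraries lay on opposite sides of the first principal component, so this comparison cannot be told apart from the difference that also separated the Control libraries. The authors' table lists 2974 genes here, 2293 higher and 681 lower, and in 2586 of them (87.0%) the groups did not overlap.

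**Figure D3:**
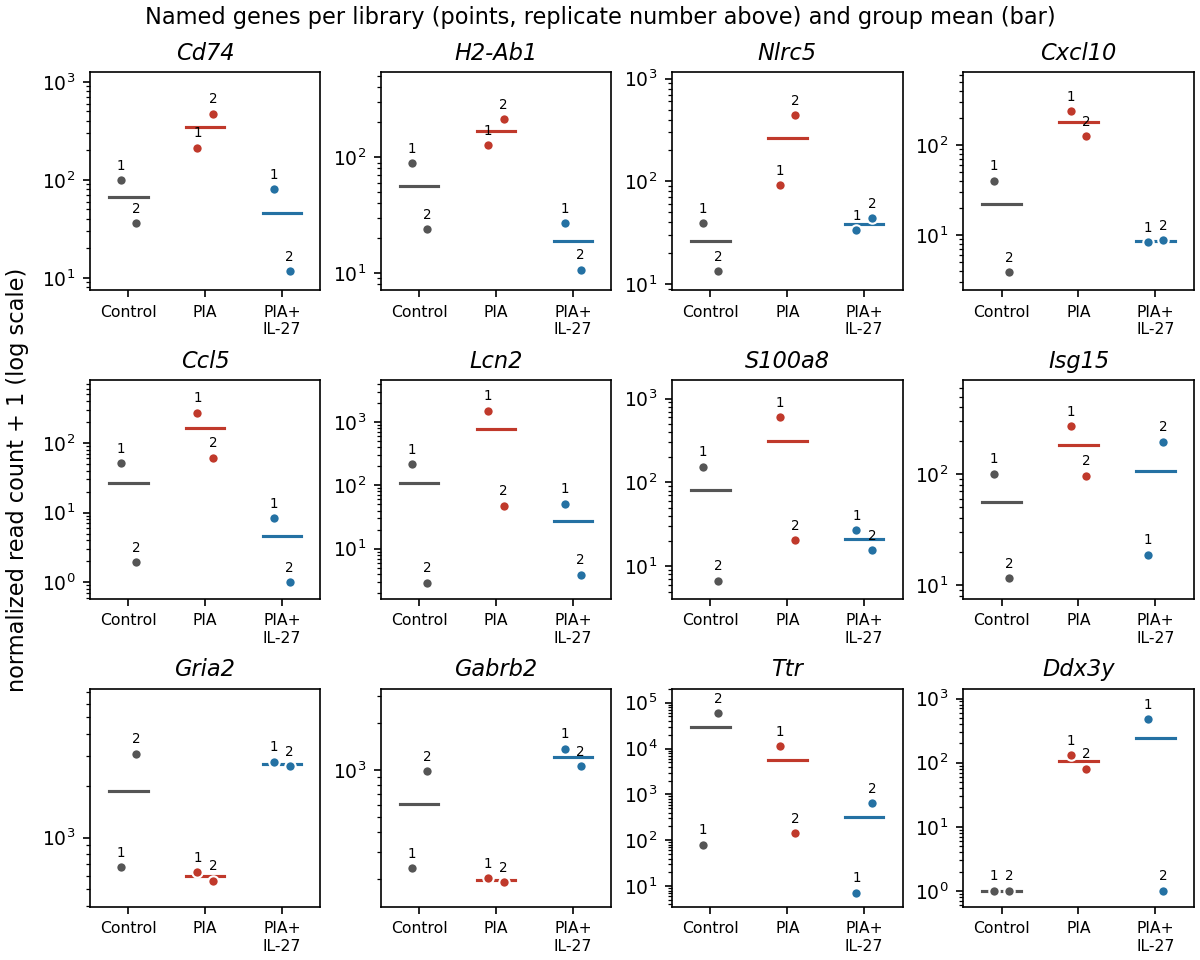
Normalized read counts plus 1 (log scale) of named genes in the 6 libraries, with points for libraries and bars for group means. Cxcl10 had 238 and 124 normalized read counts in PIA, above 39.2 and 2.86 in Control, and Gria2 had 627 and 559 in PIA, 670 and 3073 in Control and 2756 and 2610 in PIA+IL-27.

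Against Control, choroid plexus genes were lower in PIA+IL-27. They had a median log2 fold change of -3.03 with 14 of 15 below 0 (adjusted p = 5.01e-25; adjusted p = 0.536 with an estimated correlation), with 3 passing over all genes and 11 adjusted over the list alone. The 3 were Ttr (-6.48, adjusted p = 1.24e-08), the chloride channel gene Clic6 (-4.31 ± 1.05, adjusted p = 0.0155), with 30.4 and 764 normalized read counts in Control and 14.6 and 25.2 in PIA+IL-27, and Tmem72 (adjusted p = 0.0012), which had no reads in PIA+IL-27 and was at least 39.8-fold higher in Control, at 0.979 and 119. With Tmem72 at that bound the list's median stayed at -3.03. Both PIA+IL-27 libraries lay below both Control libraries in 3 of the 15 genes and above in 0. Most reads of these genes came from Control 2: without it the list had a median of 0.21 (adjusted p = 0.0399, tested as lower) and Clic6 a log2 fold change of -0.60 (adjusted p = 0.71).

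The lists of reactive astrocytes, inflammation, neutrophils, complement, ependyma and meningeal fibroblasts were lower in PIA+IL-27 than in Control. Reactive astrocyte genes had a median of -0.96 with 9 of 10 below 0 (adjusted p = 3.94e-06), inflammatory genes -0.62 with 11 of 14 (adjusted p = 0.000345), neutrophil genes -0.92 with 7 of 7 (adjusted p = 0.000992) and complement genes -0.64 with 9 of 9 (adjusted p = 0.00247). Ependyma had -0.42 with 7 of 9 below 0 (adjusted p = 0.000292) and meningeal fibroblasts -0.55 with 5 of 7 (adjusted p = 0.000552). For these 6 lists, adjusted p = 0.536 with an estimated correlation, and 1 gene, of reactive astrocytes, passed adjusted over the list alone. Both PIA+IL-27 libraries lay below both Control libraries in 4 of the 10 listed reactive astrocyte genes, 1 of 8 neutrophil and 1 of 9 complement genes. They did so in 3 of 7 meningeal, 0 of 16 inflammatory and 0 of 9 ependyma genes. Both lay above in 1 reactive astrocyte and 2 inflammatory genes. Without Control 1, neutrophil genes turned to 1.93 (adjusted p = 0.0123), complement genes to 0.77 and inflammatory genes to 0.41 (both adjusted p = 0.128), and reactive astrocytes did not pass (-0.15, adjusted p = 0.952). Without PIA+IL-27 2, complement (-0.01, adjusted p = 0.412), inflammatory (-0.10, adjusted p = 0.0708) and meningeal genes (0.05, adjusted p = 0.412) did not pass. Without PIA+IL-27 1, the libraries left in this comparison had few Y-linked reads. These summed to 2.94 and 9.52 normalized read counts in Control and 6.80 in PIA+IL-27 2. Ependyma did not pass in that fit (0.05), and the medians of choroid plexus and complement genes were -2.93 and -0.99. With GC and length trends removed, complement (-0.61), inflammatory (-0.37), neutrophil (-0.90) and ependyma genes (-0.34) did not pass, and with TMM scaling neutrophil genes did not (-2.05). The TMM medians of reactive astrocyte, inflammatory, complement, ependyma and meningeal genes were -1.98, -1.79, -1.66, -0.93 and -1.30. With the term for PIA 2 and PIA+IL-27 1, ependyma (-0.30, adjusted p = 0.0767) and neutrophil genes (-0.30, adjusted p = 0.277) did not pass.

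Type I interferon genes were higher in PIA+IL-27 than in Control, with a median of 1.05 and 16 of 17 above 0 (adjusted p = 0.0147; adjusted p = 0.614 with an estimated correlation). Both PIA+IL-27 libraries lay above both Control libraries in 3 of these 17 genes and below in 0. Ifit3, an interferon-induced antiviral gene, had 45.1 and 16.2 normalized read counts in Control and 51.1 and 253 in PIA+IL-27 (2.33 ± 0.993, adjusted p = 0.835). The list's direction turned without PIA+IL-27 2 (-0.43, adjusted p = 0.0377), and without Control 2 it was tested as lower with a median of 0.72 (adjusted p = 0.0399); with TMM scaling it did not pass (0.16). The MHC and interferon gamma list had 8 of 17 above 0, a median of -0.08 and did not pass (adjusted p = 0.115). Its median was -1.18 with TMM scaling, where it did not pass either, and with the term for PIA 2 and PIA+IL-27 1 it passed as lower (-0.44, adjusted p = 0.00335). It was higher than in Control 2 alone, without Control 1 (0.97, adjusted p = 7.99e-06), and lower than in Control 1 alone, without Control 2 (-0.63, adjusted p = 9.63e-07). The 7 other lists did not pass: GABA 0.77 (adjusted p = 0.155), glutamatergic synapse 0.57 (adjusted p = 0.188), neocortex 1.16 (adjusted p = 0.173, 1 gene adjusted over the list alone), adult neurogenesis 0.05 with a mean of -0.00 (adjusted p = 0.0944), homeostatic microglia 0.76 (adjusted p = 0.248), activated microglia 0.32 with a mean of -0.21 (adjusted p = 0.166) and the glucocorticoid response 0.14, tested as lower (adjusted p = 0.248). With TMM scaling the adult neurogenesis, activated microglia and glucocorticoid medians were -0.47, -0.90 and -0.74. Without Control 2 the glutamatergic (1.64, adjusted p = 0.0201), GABA (1.74, adjusted p = 0.0149) and activated microglia lists (-0.35, adjusted p = 0.0399) passed, and without PIA+IL-27 2 the neocortex (1.84, adjusted p = 0.0218) and adult neurogenesis lists (-1.18, adjusted p = 0.0032) did.

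Among single genes, 10 of 3216 passed in PIA+IL-27 against Control, 6 higher and 4 lower. The higher ones included the 4 Y-linked genes, read in PIA+IL-27 1: Ddx3y was at least 164-fold higher (adjusted p = 4.88e-07), Kdm5d at least 80.6-fold (adjusted p = 1.1e-05), Eif2s3y had a log2 fold change of 5.70 ± 1.13 (adjusted p = 0.000394) and Uty 157 and 0.971 normalized read counts (adjusted p = 0.0012). Entpd4 and the ion channel gene Trpa1 were the other 2, outside the rule for named genes and named after their values were seen. The lower ones were Ttr, Clic6, Tmem72 and Gdf1 (-4.50 ± 1.01, adjusted p = 0.00374). The transcription factor Mef2c had 2.65 (adjusted p = 0.206) and did not pass. There were 92 genes at an unadjusted p under 0.05, 53 of them higher, and the median of all genes was 0.55; with TMM over the listed genes edgeR called 0, with 118 at an unadjusted p under 0.05 of which 5 were higher, and the median was -0.02. DESeq2 called 1 and limma 1. The count was 0 without Control 1 or without Control 2 (109 and 1193 genes at an unadjusted p under 0.05), 6 without PIA 1 or PIA 2, and 2 without PIA+IL-27 1. The authors' table lists 815 genes, 495 higher and 320 lower, with no overlap between the groups in 467 (57.3%).

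The genes given here were chosen in advance for every comparison and did not pass in any. Il27 had 0.979 and 0.952 normalized read counts in Control, 2.88 and 7.64 in PIA and 1.04 and 0 in PIA+IL-27, too few to be tested. Ebi3, which encodes the other subunit of IL-27, had log2 fold changes of 1.23 in PIA against Control (adjusted p = 0.617), -0.87 in PIA+IL-27 against PIA (adjusted p = 0.431) and 0.36 in PIA+IL-27 against Control (adjusted p = 0.862). Tnf had log2 fold changes of 2.48, -3.12 and -0.64 in the same order, and Il1b 1.95, -3.28 and -1.33. Socs3, an inhibitor of cytokine signalling, had 0.98, -2.12 and -1.14, the astrocyte filament gene Gfap 0.31, -1.44 and -1.13, and the neurotrophin Bdnf -1.67, 1.84 and 0.18. Il27ra, Il6st, Stat3, Aif1 and Il6 are outside the table and not analysed here.

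The comparisons that share the PIA libraries had opposite fold changes at most genes. Across 3216 genes, which are not independent replicates, the log2 fold changes of PIA against Control and PIA+IL-27 against PIA had a Pearson r of -0.75, a Spearman rho of -0.74 and a covariance of -1.40, with opposite signs at 91.4% of genes. Sharing PIA libraries makes part of this. In 20 simulated sets of unchanged groups, the mean r was -0.50, the covariance -0.47 and the share of opposite signs 66.4%. Choosing simulated genes by an absolute log2 fold change of at least 1 in any comparison gave -0.50, -0.80 and 66.8%. The Q value behind the table was not applied to them. Simulated genes were drawn independently, so a library difference shared by many genes was not simulated. Each gene also had the same spread in all groups. Replicates differed by over 2-fold at 68.8% of listed genes in Control, 31.4% in PIA and 31.0% in PIA+IL-27. The r that sharing PIA gives at such unequal spreads was not simulated, and this holds for the fits with a library left out. Of the 7 genes that passed in PIA against Control, 4 had the opposite sign in the second comparison, and the 2 that passed in both, Hmga1b and Gm45855, were opposite. Hmga1b is a near-identical copy of Hmga1, and the number of shared calls that sharing PIA alone would give was not simulated. Without Control 2 the r was -0.39, against a mean of -0.37 over 20 simulated sets of those 5 libraries, and without PIA+IL-27 2 it was -0.56 against -0.38. Without Control 1 and without PIA+IL-27 1 the r was -0.80 and -0.74, both against -0.38. Without PIA 1 and without PIA 2 it was -0.79 and -0.78, both against -0.72.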

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

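The robust spread, the removal of GC and length trends, the region term, the fit without PIA 2 and PIA+IL-27 1, and the adjustment over protein-coding genes were chosen after the data were seen; the other alternatives were planned. With 2 libraries per group, the counts of genes changed under most alternatives, and the cause of each change was not tested. In the order PIA against Control, PIA+IL-27 against PIA and PIA+IL-27 against Control, the counts of 7, 14 and 10 genes became 0, 0 and 0 with TMM, with median-of-ratios factors, with GC and length trends removed, and without PIA 2 and PIA+IL-27 1 (edgeR; 117, 591 and 118 genes at an unadjusted p under 0.05 with TMM, 111, 579 and 110 with median-of-ratios factors, 128, 221 and 46 with trends removed, and 40, 74 and 34 without the 2 libraries). They became 2, 4 and 1 with DESeq2, 6, 9 and 1 with limma and 1 TPM added, 11, 14 and 5 with 0.1 TPM added, 4, 8 and 7 with a robust spread, 6, 8 and 7 over all protein-coding genes, 9, 449 and 1 with only the libraries of the comparison, and 9, 16 and 11 without a filter. With each library left out in turn, each of the 3 counts ran from 0 to 7, and the lone library left in a group was assumed to vary like the others.

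With replicate number as a block, the counts were 3, 4 and 3 genes. The labels state no pairing by number. Deviations of libraries of the same number correlated across genes at 0.094, -0.306 and 0.099, which cannot show whether the samples were paired. With this block, choroid plexus (-1.12, adjusted p = 0.0859) and adult neurogenesis genes (-1.10, adjusted p = 0.0556) did not pass in PIA against Control. With a region term, which also pairs PIA and PIA+IL-27 in crossed order, the counts were 9, 2 and 3.

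Of the 9, 10 and 8 lists that passed with the preset correlation, 0, 0 and 0 passed with an estimated correlation. With single libraries left out the counts of lists ran from 5 to 10, from 7 to 11 and from 6 to 12; in PIA+IL-27 against Control 4 passed with GC and length trends removed. Over all lists and alternatives, 664 results kept their direction and side of the threshold, 73 lost their call, 19 gained one and 12 reversed by the direction of the test; for the named genes the numbers were 1300, 199, 14 and 0. The r of opposite changes ran from -0.80 without Control 1 to -0.39 without Control 2, with -0.56 without PIA+IL-27 2.

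The reversals came with left-out libraries, and their medians are given with the range over single libraries left out. In PIA against Control, choroid plexus had 1.20 without Control 2 (range -4.06 to 1.20) and neutrophils 0.78 without Control 2 (-1.41 to 4.37). In PIA+IL-27 against PIA, type I interferon genes had 0.63 without PIA+IL-27 1 (-1.61 to 0.63) and ependyma -1.04 without PIA+IL-27 2 (-1.04 to 2.14). In PIA+IL-27 against Control and without Control 1, complement genes had 0.77 (-1.01 to 0.77), inflammatory genes 0.41 (-1.20 to 0.41), MHC genes 0.97 (-0.63 to 0.97) and neutrophils 1.93 (-2.03 to 1.93). In the same comparison type I interferon genes had 0.72 without Control 2 and -0.43 without PIA+IL-27 2 (-0.43 to 2.18), and ependyma 0.05 without PIA+IL-27 1, with or without PIA 2 (-2.62 to 0.52). Each rests on fewer samples, and beyond that the cause was not tested.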

Other observations

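Among the genes of cell types with fewer than 5 tested members, several had fold changes on opposite sides of 0 in the 2 comparisons that share PIA, as did the table as a whole, whose medians over all tested genes were -0.68 and 1.17. Both tested oligodendrocyte genes, both genes of oligodendrocyte precursors, all 3 listed astrocyte genes and both genes of presynaptic vesicle release had log2 fold changes below 0 in PIA against Control (medians -1.46, -1.27, -0.91 and -0.74) and above 0 in PIA+IL-27 against PIA (medians 2.16, 2.04, 1.15 and 1.44). The 4 genes of neurotrophins and monoamines had medians of -1.12 and 1.72, and both proliferation genes -1.42 and 1.79. None of these genes passed. All of them were higher in Control 2 than in Control 1. Vascular genes went both ways: 2 of 4 endothelial genes and 2 of 4 genes of pericytes and smooth muscle were above 0 in PIA against Control, with medians of -0.06 and -0.49. The tested genes of the list for the IL-27 receptor and its signalling had a median of 1.08 in PIA against Control, with 3 of 4 above 0. Their median in PIA+IL-27 against PIA was -0.49. The receptor genes Il27ra and Il6st are outside the table, so these medians do not measure the receptor. Without the filter on low counts this list had 5 members. At the preset correlation it then passed as higher in PIA against Control (adjusted p = 0.0254, camera) and as lower in PIA+IL-27 against PIA (-0.86, adjusted p = 0.0446). An estimated correlation, with which no list passed in the main fit, was not run without the filter.

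The table lists 17 of the 17 genes fixed for MHC and interferon gamma and 15 of the 15 fixed for the choroid plexus. It lists 0 of 26 genes of nuclear-encoded oxidative phosphorylation, 0 of 27 cytosolic ribosomal proteins, 0 of 13 mitochondrially encoded genes, 0 of 16 immediate early genes and 0 of 5 blood genes. Of the collagen genes of meningeal fibroblasts, Col1a1 had 1041 and 762 normalized read counts in PIA+IL-27 against 3858 and 1461 in Control (log2 fold change -1.56 ± 0.816, adjusted p = 0.835), and Col3a1 1390 and 935 against 2548 and 2322 (adjusted p = 0.835). Dcx, a marker of immature neurons, had 4898 and 2897 in PIA and 10422 and 9443 in PIA+IL-27 (adjusted p = 0.278).

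Of the tests that follow, only the one adjusted for GC content and length was written before its result was seen; the others were chosen after. Most listed genes were higher in PIA+IL-27 than in PIA. Treatment alone would not order the Control libraries, yet 96.2% of the 2293 genes that the authors list as higher in PIA+IL-27 were higher in Control 2 than in Control 1, against 41.6% of the other 1440. Across 2659 genes the log2 ratio of Control 2 to Control 1 followed that of PIA+IL-27 to PIA with a Spearman rho of 0.740, so a difference between libraries that is also present within Control may account for much of this pattern. After adjustment for linear and squared ranks of GC content and transcript length, the rho was 0.565, against 0.741 before, over 2575 genes. This argues against GC content and length as all of that difference but cannot exclude it. Levels changed steeply with GC content, which such ranks may not follow. Control 2 lay at 0.595 in bin 8 of GC content and at -0.362 in bin 9. What the difference is stays open, in the tissue, in the libraries or as a wrong label of a Control library, which was not tested and bears on every comparison, and an effect of IL-27 in addition to it was not separable.

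The MHC and inflammatory genes were higher in PIA than in the other groups. Whether GC and length trends are the whole cause could not be decided. The smooth trends that were removed may not follow the steep change in levels between bins 8 and 9 of GC content. With those trends removed, the MHC median in PIA+IL-27 against PIA was -1.31 (-2.14 before), and the list passed at the preset correlation. At an estimated correlation the MHC list did not pass in the main fit. Neutrophils or a strong response in PIA 1 alone are argued against for the MHC list, within these libraries. Without PIA 1 the MHC median in PIA against Control was 2.18, while the neutrophil median was -1.41. Both values rest on PIA 2 as the only PIA library, which had high neocortical and low dentate markers. For the inflammatory list the argument against PIA 1 alone holds in part, with the same limit. Its medians without PIA 1 were 0.89 (1.52 before) and, in PIA+IL-27 against PIA, -1.17 (-1.91 before). The library difference that separates the Control libraries stays open for part of the size, because all 17 genes were lower in Control 2 (median log2 ratio -1.45) and PIA and PIA+IL-27 lie on opposite sides of that difference, so that it and the treatment cannot be told apart for this list; against Control 1, which lies on the same side as PIA, the median was 1.34 (adjusted p = 1.01e-08). Immune activation and IL-27, the treatments that the design names, stay open as explanations and were not separately tested, as does the sex of the animals in PIA against Control.

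The Y-linked genes called higher than in Control may come from the sex of the animals. All 4 listed Y-linked genes were at least 5-fold higher in each of PIA 1, PIA 2 and PIA+IL-27 1 than in each other library. Libraries from male and from female animals would give such a split. PIA 1, PIA 2 and PIA+IL-27 1 were picked by the sum of these same 4 genes, so only the sharing of the split by all 4 was tested. The labels give no sex. The table lists 4 of the 5 fixed sex-linked genes, and Xist is not analysed here. No gene outside the Y chromosome was used to check this reading.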
